A study of Mus musculus with 6 samples.

How the data were processed

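Polyadenylated RNA of sciatic nerve from mice at postnatal day 14 was sequenced in 6 libraries, 3 from control mice (homozygous floxed RhoA) and 3 from icKO mice (the same with ChAT-CreERT2). Groups and replicate numbers were taken from the labels. The labels do not state the sex, litter, collection day or induction schedule of the mice, whether control mice also received the drug that induces Cre, nor that the libraries of a group came from separate animals.

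The authors deposited 1 table of FPKM values for 55335 genes in the 6 libraries, with Ensembl gene IDs. Per the submitters' processing notes, FastQC 0.11.2, STAR, StringTie 1.3.1c, DESeq2 1.16.1 and the mouse build GRCm39 were used, without a role or an order for each. The annotation release, the handling of strand and of reads with several matches are not given in the sources used here. FPKM values are fragments divided by the total of the library and by transcript length, so a few very abundant transcripts lower all others, and genes with near-identical copies or overlapping neighbours can share fragments. The 6 columns were each matched to a sample by name, and none was left over. Gene symbols came from GENCODE release M21, an annotation of another build (GRCm38), matched by gene ID for 55154 of the IDs, and 181 IDs had no match. Because the builds differ, that annotation was used only for symbols, transcript lengths and GC content, and no coordinates are given.

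The table holds no counts. The depth was estimated from the lowest FPKM values, since a gene's FPKM moves in steps of what 1 fragment is worth. In the 34186 genes with 1 annotated transcript, the most frequent product of low FPKM (under 0.3) and transcript length between 35 and 80 was read as 1 fragment, in 514 to 598 genes per library, which gave 17200000 to 20600000 fragments. Genes near the filter therefore rest on few fragments where their transcripts are short, and carry more counting error. StringTie values are estimates from assembled transcripts, and whole fragments were not recovered, so no count model was used.

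Each gene was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a two-sided moderated test, a variance trend, equal weights and no covariate, over the 12860 genes with a mean of at least 1 FPKM across the 6 libraries. P-values were adjusted by the Benjamini-Hochberg method over these genes, and a gene was called at an adjusted p under 0.05. A difference on the log2(FPKM + 1) scale understates the change of low genes. In text, rose and fell refer to calls in the icKO group relative to control. Gene lists were tested with camera from limma on the same values, with a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 37 lists with at least 5 tested members. Estimated correlations and fry, which tests whether the genes of a list move one way on balance, were computed beside it. With an estimated correlation no list had an adjusted p under 0.05. For each list, the number of members called was also computed with p-values adjusted over the list alone. Of 805 list entries 800 were matched to a gene ID.

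The groups, the test, the filter, the pseudocount, 43 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule always names Rhoa, Chat, Egr2 and a set of myelin genes. Among called genes whose groups do not overlap it adds the 10 largest rises and the 10 largest falls, leaving out gene models without a symbol, of which 571 were among the 5516 calls. It also adds, from each list called by camera, the 3 members with the smallest p in the direction of the list and any called member that moved the other way. Of the genes chosen by the rule 59 are reported, 58 of which passed the filter. A few others and 1 gene list, tested with the rest, are not reported here. Sex-linked genes serve only as a check of the libraries.

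The alternatives were pseudocounts of 0.1 and 0.01, no filter or a mean of at least 5 FPKM, rescaling to a common sum (TPM), median-of-ratios and quantile scaling, a replicate block, limma without a trend, with robust estimation or with array weights, an adjusted p of 0.1, and leaving out each library in turn. A fit without the control and the icKO library richest in muscle transcripts and a correction of each library's log2 values for trends with GC content and transcript length (loess, span 0.5, with values for 99.9% of the tested genes) were added after the data were seen. So was a fit with each library's mean log2(FPKM + 1) of the tested skeletal muscle genes as a covariate. The main fit and camera were run on all 10 splits of the 6 libraries into 3 and 3. The procedure was tested on simulated data for the comparison of icKO with control over 12860 genes. In that simulation 200 genes were changed, and 77% of changes of 1 and 97% of changes of 2 on the log2 scale were recovered, with 9 false calls. Smaller changes, or changes in as many genes as were called in the data, were not simulated. The calls in the data had a median absolute log2 difference of 0.59. Camera called a shifted list of 25 genes and none of 20 unshifted lists. The simulated genes varied independently of each other, so the simulation cannot test camera on lists whose genes vary together. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.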

Results

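Polyadenylated RNA was sequenced from lysates of mouse sciatic nerve, the large mixed nerve of the hindlimb, collected at postnatal day 14, when Schwann cells are forming myelin around the larger axons. Control nerves (n = 3) came from mice homozygous for a floxed RhoA allele, and icKO nerves (n = 3) from mice that also carried ChAT-CreERT2, an inducible Cre recombinase expressed from the choline acetyltransferase gene and thus in cholinergic neurons such as spinal motoneurons. The comparison asks what a deletion of the small GTPase RhoA aimed at motoneurons does to the transcripts of the nerve in which their axons run. The labels do not state when the deletion was induced. A sciatic nerve lysate contains RNA from Schwann cells, fibroblasts, perineurial and vascular cells, macrophages, fat and, to a small extent, axons, while the motoneuron cell bodies lie in the spinal cord. Values are FPKM, fragments normalised to transcript length and library depth. From the smallest steps of these values, the depth was estimated at 17200000, 20600000 and 20600000 fragments in the 3 control libraries and 17800000, 19000000 and 19500000 fragments in the 3 icKO libraries. Between 12394 and 12830 genes reached 1 FPKM in a library. Xist was at 46.1 FPKM in control replicate 2 and at 0.028 FPKM or less in the other 5 libraries, where the Y-linked gene Ddx3y was at 12.5 to 16.1 FPKM. These transcripts mark control replicate 2 as female and the other 5 libraries as male, so only the control group holds both sexes.

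The floxed gene was measured first. Rhoa (ENSMUSG00000007815) was at 37.9 ± 1.24 FPKM (SD, n = 3) in control and 34.4 ± 1.75 FPKM (SD, n = 3) in icKO nerves. The difference of -0.13 on the log2(FPKM + 1) scale (SE 0.08) did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.195), although all 3 icKO libraries lay below the 3 control libraries. Most Rhoa transcript of a nerve comes from cells that the Cre driver does not target, so the level in lysate is a weak check of the labels. Chat, the gene of the Cre driver, was at 0.012 FPKM in control replicate 1 and listed at 0 in the other 5 libraries, below the filter for testing.

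The nerves of the 2 genotypes differed in a large part of the transcriptome. Of 12860 genes tested, 5516 (42.9%) passed a Benjamini-Hochberg adjusted p of 0.05 in limma, 2670 of them higher and 2846 lower in icKO nerves. The rises were 20.8% of all tested genes. Counts of list members below are to be read against these shares, since a list with a like share does not stand out. Of these, 977 differed by at least 1 on the log2(FPKM + 1) scale, which understates the change of low genes. Unadjusted p under 0.05 together with a log2 difference of at least 1 held for 1003 genes, 470 higher and 533 lower. In 7362 genes (57.2%, where chance gives 10%) the libraries of the 2 groups did not overlap. The first principal component held 66% of the variance and separated the groups, and the second, with 14.9%, set icKO replicate 3 apart. Correlations between libraries were 0.953 to 0.982 within groups and 0.889 to 0.914 between them. Control replicate 1 and icKO replicate 3 were the libraries richest in skeletal muscle transcripts, with Acta1 at 309 and 771 FPKM against 2.15 to 80.6 FPKM in the other 4 libraries, and with each library's mean log2 level of skeletal muscle genes as a covariate 4802 genes passed. The labels do not say that the libraries of a group came from separate animals, so all p-values measure only the spread between these samples. Xist and Ddx3y show that control replicate 2 came from another animal than control replicates 1 and 3. The rest of the spread may be technical.

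**Figure D1:**
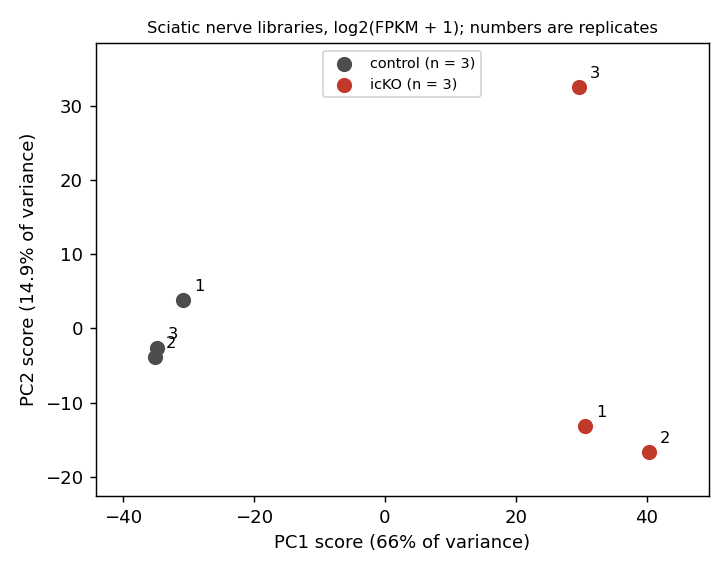
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 1), with control libraries in grey, icKO libraries in red and replicate numbers beside the points. The first component (66% of the variance) separates the groups, and icKO replicate 3 lies apart at 32.5 on the second (14.9%).

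The largest rise was that of Mt2 (ENSMUSG00000031762), a gene of the metallothioneins, small metal-binding proteins. It rose from 107 ± 59.2 to 1962 ± 188 FPKM (SD, n = 3 each), a log2 difference of 4.31 (SE 0.35, limma, Benjamini-Hochberg adjusted p = 0.000607). Another metallothionein gene, Mt1, rose from 72.4 ± 19.6 to 825 ± 96.0 FPKM. Hif3a, a hypoxia-inducible factor subunit, rose from 1.5 ± 0.60 to 27.2 ± 5.58 FPKM. The sodium-proton exchanger gene Slc9a3 rose from 8.35 ± 4.00 to 117 ± 29.8 FPKM, and Plin4, which encodes a lipid droplet coat protein, from 10.7 ± 0.49 to 85.1 ± 28.9 FPKM. The other 5 of the 10 largest rises were Otulinl (1.44 to 22.7 FPKM), Arrdc2 (7.71 to 76.9 FPKM), Rilp (2.33 to 25.5 FPKM), Map3k6 (2.57 to 25.6 FPKM) and Slc10a6 (1.52 to 17.2 FPKM), each with an adjusted p of 0.000634 or less. Among the largest falls, Cnmd fell from 16.8 ± 3.37 to 0.57 ± 0.19 FPKM, the carbonic anhydrase gene Car3 from 198 ± 30.0 to 24.1 ± 22.9 FPKM and Orm1 from 11.01 ± 4.01 to 0.17 ± 0.11 FPKM. Cyp2e1 fell from 40.5 ± 3.41 to 3.62 ± 2.01 FPKM, Lctl from 33.2 ± 1.70 to 2.78 ± 0.36 FPKM, and Thrsp, a gene of lipid-forming cells, from 31.0 ± 15.1 to 2.90 ± 1.62 FPKM. The chemokine gene Ccl21a was at 12.5, 31.0 and 21.8 FPKM in the control libraries and at 0.85, 0 and 2.74 FPKM in the icKO libraries. Kctd12 was at 5.17, 9.22 and 8.56 FPKM in control and listed at 0 in all 3 icKO libraries. Of the tested genes, 18 were listed at 0 in a library and at 10 FPKM or more in another. Some of these zeros can be real, as muscle genes such as Myl2 and the Y-linked Ddx3y are among the 18. The broadly expressed linker histone gene H1fx was also among them, at 0 in control replicate 2, so a listed 0 can be a failed estimate. Levels of Ccl21a and Orm1, which have near-identical copies, are uncertain.

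The largest fall of all was that of the muscle gene Actc1, and the muscle gene Pvalb was also among the 10 largest. Actc1 was at 101, 13.2 and 22.7 FPKM in control and at 0, 0.03 and 0.79 FPKM in icKO libraries, and Pvalb at 134, 27.3 and 42.0 against 3.13, 3.66 and 10.4 FPKM. The skeletal muscle list holds Pvalb but not Actc1. Its gene Ckm, muscle creatine kinase, was at 151, 25.7 and 38.1 FPKM in control and at 0.40, 1.82 and 100 FPKM in icKO libraries. Of the 21 tested members of the list only Pvalb passed (1 when adjusted over the list alone), with a median log2 difference of -2.18 (camera, Benjamini-Hochberg adjusted p = 0.29), while 14 fell once icKO replicate 3 was left out.

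Myelin structure genes moved in both directions or did not pass. As 42.9% of all tested genes passed, the calls in this list do not set it apart. Pmp22 was at 10050 ± 1047 FPKM in control and 11570 ± 1152 FPKM in icKO nerves, and Mbp at 921 ± 62.5 and 735 ± 166 FPKM (SD, n = 3 each). Neither difference passed (limma, Benjamini-Hochberg adjusted p = 0.241 and 0.157). Mag, an adhesion protein of the inner myelin membrane, fell from 111 ± 11.9 to 65.4 ± 8.54 FPKM, a log2 difference of -0.76 (SE 0.13, adjusted p = 0.00446). Prx, the periaxin gene, was at 1013 ± 48.5 and 845 ± 2.26 FPKM, a fall with an adjusted p of 0.0416. It no longer passed whichever single library was left out, or with median-of-ratios or quantile scaling, the replicate block or the muscle covariate (limma adjusted p = 0.075 to 0.11). Nor did it pass without a filter or without the 2 muscle-rich libraries (limma adjusted p = 0.28 and 0.14, and 0.03 to 0.28 over all alternatives). Of 17 tested myelin structure genes, 3 rose, with Gjc3 and Ncmap among them, 3 fell (Mag, Pmp2 and Prx) and 11 did not pass, with the same counts when adjusted over the list alone. The list did not pass as a set (camera, Benjamini-Hochberg adjusted p = 0.94). Pmp2, which encodes a fatty acid-binding protein of myelin, was at 812 ± 23.7 and 290 ± 180 FPKM (adjusted p = 0.0331) and passed in only 2 of the 6 fits that left out a single library, those without icKO replicate 2 or 3. With quantile scaling the difference of Pmp22 was 0 on the log2 scale.

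Regulators of myelination moved in both directions, in data where 42.9% of all tested genes passed and 20.8% rose. Egr2, the transcription factor of the myelinating Schwann cell, varied too widely to test well, at 10.8, 9.32 and 41.2 FPKM in control and 75.0, 11.7 and 62.6 FPKM in icKO libraries (limma, Benjamini-Hochberg adjusted p = 0.271). Of 17 tested regulators, 3 rose (Pou3f1, Dicer1 and Yy1), 6 fell (Adgrg6, Nab1, Nab2, Gpr37l1, Smarca4 and Pou3f2) and 8 did not pass, with 3 and 6 adjusted over the list alone. Adgrg6, an adhesion receptor that Schwann cells need to start myelination, fell from 9.60 ± 0.39 to 5.28 ± 0.11 FPKM, and Nab2, a partner of Egr2, from 23.4 ± 0.98 to 17.2 ± 0.94 FPKM. Sox10 was at 169 ± 5.37 and 175 ± 19.4 FPKM. Among 10 tested genes of neuregulin and ErbB signalling, through which axons signal to Schwann cells, 4 rose (Erbb2, Erbb3, Erbin and Grb2) and 3 fell (Adam10, Adam17 and Erbb4), also when adjusted over the list alone. The receptor genes Erbb2 and Erbb3 rose from 19.2 ± 1.68 to 35.8 ± 2.86 FPKM and from 43.8 ± 2.43 to 63.3 ± 3.78 FPKM. The sheddase gene Adam10 fell from 144 ± 8.81 to 75.0 ± 0.98 FPKM (SD, n = 3 each). Neither list passed as a set (camera, Benjamini-Hochberg adjusted p = 0.37 and 0.79). Smarca4 and Pou3f2 passed in only 2 and Grb2 in only 1 of the 6 fits that left out a library, and Yy1 and Pou3f1 did not pass without control replicate 2 or 3. Members of lists named here and in the paragraphs that follow, beyond the fixed rule, were chosen after their values were seen.

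Genes of cholesterol synthesis, which supplies the sterol of growing myelin, fell almost as a block. Of 25 tested, 24 fell and 1 rose, also when adjusted over the list alone, with a median log2 difference of -1.38. Idi1 fell from 125 ± 19.1 to 33.3 ± 4.17 FPKM, Sc5d from 76.7 ± 3.72 to 21.3 ± 4.14 FPKM and Cyp51 from 94.8 ± 13.4 to 23.9 ± 4.41 FPKM (SD, n = 3 each), all enzymes of the pathway. The member that rose was Lbr, which encodes a sterol reductase that is also the lamin B receptor of the nuclear envelope, from 9.45 ± 0.68 to 20.4 ± 4.15 FPKM. The list passed as a set with a preset correlation (camera, Benjamini-Hochberg adjusted p = 8.2e-10), and had an adjusted p = 0.94 with an estimated correlation. Fatty acid and sphingolipid synthesis followed with 16 of 25 tested members lower, 3 higher and 6 that did not pass, the same counts as adjusted over the list alone, and a median of -0.61. Elovl6 fell from 84.5 ± 6.96 to 24.3 ± 3.46 FPKM, the malic enzyme gene Me1 from 54.5 ± 9.50 to 15.0 ± 1.56 FPKM and Elovl7 from 47.7 ± 3.37 to 19.7 ± 2.56 FPKM. Kdsr, Srebf1 and Ugcg rose, Srebf1 from 19.2 ± 2.07 to 31.4 ± 0.97 FPKM. Kdsr did not pass without control replicate 2 or 3 or with the muscle covariate (limma, Benjamini-Hochberg adjusted p = 0.066, 0.067 and 0.051, and 0.0076 to 0.067 over all alternatives). This list had a camera adjusted p of 0.0015 (Benjamini-Hochberg), and an adjusted p = 0.94 with an estimated correlation. Adipocyte transcripts fell in the same libraries.

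Of 14 tested adipocyte genes, 10 fell, 2 rose and 2 did not pass (11 fell and 2 rose when adjusted over the list alone), with a median log2 difference of -0.90. Plin1, a lipid droplet protein of fat cells, fell from 11.1 ± 1.45 to 1.43 ± 0.63 FPKM, and the secreted products Retn and Cfd fell from 16.3 ± 2.32 to 1.39 ± 0.76 FPKM and from 369 ± 60.7 to 68.7 ± 19.4 FPKM (SD, n = 3 each). Adipoq was at 45.9, 50.1 and 52.8 FPKM in control and at 9.79, 6.12 and 13.0 FPKM in icKO libraries. Plin4 and the lipase gene Pnpla2 rose, the latter from 48.4 ± 5.55 to 74.6 ± 9.11 FPKM. As a set the adipocyte list passed (camera, Benjamini-Hochberg adjusted p = 0.0068), with an adjusted p = 0.94 with an estimated correlation.

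**Figure D2:**
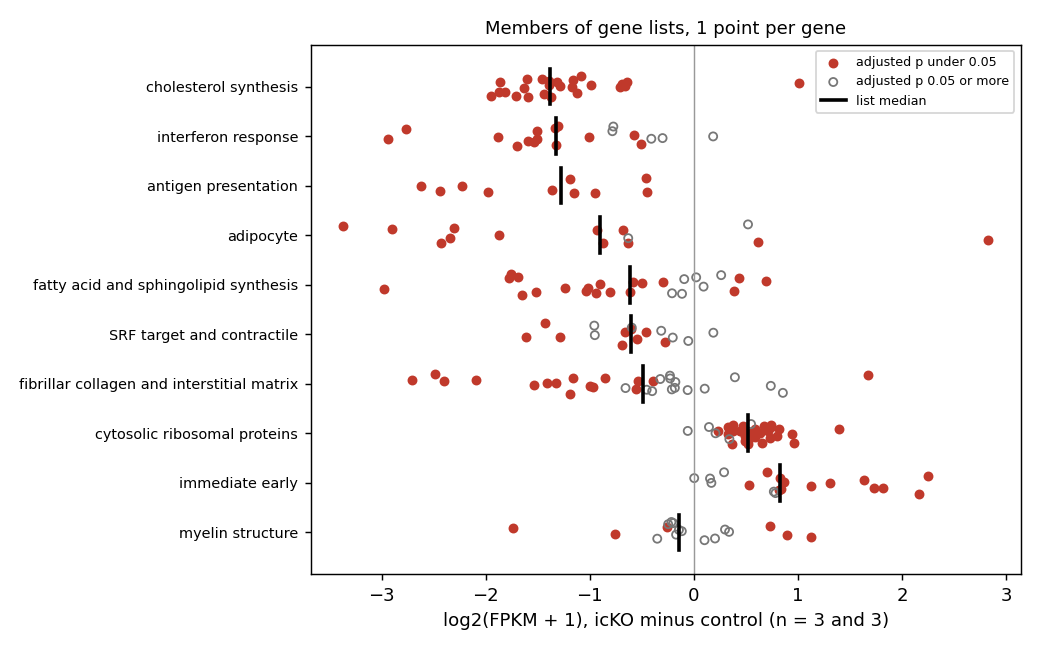
Difference in log2(FPKM + 1), icKO minus control, for each tested member (1 point per gene, n = 3 libraries per group) of the 9 lists that camera called and of the myelin structure list, with filled points for limma Benjamini-Hochberg adjusted p under 0.05 and a bar at the list median. Cholesterol synthesis lies lowest by median at -1.38 and immediate early genes highest at 0.83, while the myelin structure genes spread on both sides of 0.

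Genes of antigen presentation and of the interferon response were lower in icKO nerves. All 10 tested genes of antigen presentation fell, also when adjusted over the list alone, with a median log2 difference of -1.28. H2-K1, a class I histocompatibility gene, fell from 39.3 ± 2.03 to 16.7 ± 1.51 FPKM. H2-DMa and H2-DMb1, which serve peptide loading of class II molecules, fell from 22.7 ± 0.92 to 9.70 ± 1.11 FPKM and from 66.8 ± 3.88 to 25.7 ± 5.64 FPKM (SD, n = 3 each). Of 19 tested genes of the interferon response 14 fell (15 when adjusted over the list alone), none rose and 5 did not pass, with a median of -1.32. Ifi27l2a fell from 26.4 ± 7.55 to 2.99 ± 0.95 FPKM. Bst2 fell from 38.0 ± 13.3 to 11.4 ± 0.78 FPKM. The sets passed with camera's preset correlation (Benjamini-Hochberg adjusted p = 3.4e-05 and 5.7e-05), each with an adjusted p = 0.94 with an estimated correlation. Of 17 tested macrophage markers, with a median of -0.37, only Mertk passed, also when adjusted over the list alone, a rise from 14.9 ± 2.11 to 43.2 ± 7.31 FPKM (camera, Benjamini-Hochberg adjusted p = 0.71), although 11 macrophage genes fell without control replicate 1, and 11 without the 2 muscle-rich libraries, of which it is 1. Histocompatibility genes are a multigene family whose members can share reads.

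The interstitial matrix list fell in part. Of 30 tested members, 15 fell, 1 rose and 14 did not pass, with 15 and 1 adjusted over the list alone and a median log2 difference of -0.49. When single libraries were left out, 11 to 17 fell and 1 or 2 rose. Without the 2 muscle-rich libraries 18 fell and 1 rose. Col14a1 (ENSMUSG00000022371), a fibril-associated collagen, fell from 60.9 ± 2.80 to 10.0 ± 0.20 FPKM, a log2 difference of -2.49 (SE 0.07) with the smallest adjusted p of all genes together with Lctl (limma, Benjamini-Hochberg adjusted p = 7.21e-05). Mfap5, a microfibril protein, fell from 123 ± 10.7 to 28.0 ± 1.65 FPKM and P4ha1, a subunit of collagen prolyl hydroxylase, from 50.8 ± 2.13 to 16.9 ± 1.82 FPKM. The crosslinking enzyme gene Lox rose from 161 ± 38.4 to 508 ± 34.5 FPKM. The set passed (camera, Benjamini-Hochberg adjusted p = 0.0015), with an adjusted p = 0.94 with an estimated correlation. Fibroblast markers went both ways, with 3 of 15 higher (Apod, Etv1 and Pdgfra), 3 lower (Col15a1, Cd34 and Dpt), also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.7). Etv1 and Pdgfra each passed in only 2 and Dpt in only 3 of the 6 fits that left out a library. In these fits 1 or 2 fibroblast markers were higher, and 7 were lower without control replicate 1. Without the 2 muscle-rich libraries 3 were higher and 9 lower. Of 16 tested SRF target and contractile genes 9 fell and none rose, also when adjusted over the list alone, with a median of -0.60. Cytoplasmic actin Actg1 fell from 214 ± 8.81 to 135 ± 5.48 FPKM, the myosin light chain gene Myl9 from 157 ± 21.7 to 51.6 ± 12.9 FPKM and vinculin, Vcl, from 11.9 ± 1.87 to 6.97 ± 0.77 FPKM. The SRF set had a camera adjusted p of 0.0088 (Benjamini-Hochberg), and an adjusted p = 0.94 with an estimated correlation. Only 4 of its members fell without control replicate 2, without icKO replicate 2, with the replicate block or with the muscle covariate. Of 13 pericyte and vascular smooth muscle genes, 3 of them shared with the SRF list, 5 fell (4 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.3). Only 2 fell without control replicate 1 and 1 without icKO replicate 2. None, 0, fell without control replicate 2 or icKO replicate 1, or with the replicate block or the muscle covariate.

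Cytosolic ribosomal protein genes rose, with 31 of 36 higher, none lower and 5 that did not pass (33 higher when adjusted over the list alone), and a median log2 difference of 0.52. Rps28 rose from 10.2 ± 0.68 to 17.7 ± 0.94 FPKM, Rps18 from 35.6 ± 3.61 to 62.5 ± 1.54 FPKM and Rps23 from 81.9 ± 5.79 to 145 ± 11.1 FPKM (SD, n = 3 each). The set passed (camera, Benjamini-Hochberg adjusted p = 6.4e-10), with an adjusted p = 0.94 with an estimated correlation. Ribosomal protein genes have many processed pseudogenes that can share their reads. Immediate early genes rose as well, 13 of 19 higher, none lower and 6 that did not pass (14 higher when adjusted over the list alone), with a median of 0.83. The transcription factor gene Fosl2 rose from 3.88 ± 0.53 to 22.2 ± 3.33 FPKM. Zfp36, which encodes a protein that destabilises messenger RNA, rose from 7.76 ± 0.43 to 30.3 ± 5.87 FPKM, and the phosphatase gene Dusp1 from 5.01 ± 0.70 to 13.9 ± 2.50 FPKM. This set passed too (camera, Benjamini-Hochberg adjusted p = 7.5e-05), with an adjusted p = 0.94 with an estimated correlation. Without control replicate 3, 8 of its members rose. Such genes also respond to handling of the tissue. The ribosomal protein and immediate early lists had both been fixed as checks of quality, and an effect of RNA quality was not tested. Fos and Jun were at 19.2 ± 15.1 and 19.3 ± 9.15 FPKM in icKO nerves against 3.98 ± 0.93 and 16.0 ± 2.31 FPKM in control, of which only the rise of Fos passed, and in only 1 of the 6 fits that left out a library.

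**Figure D3:**
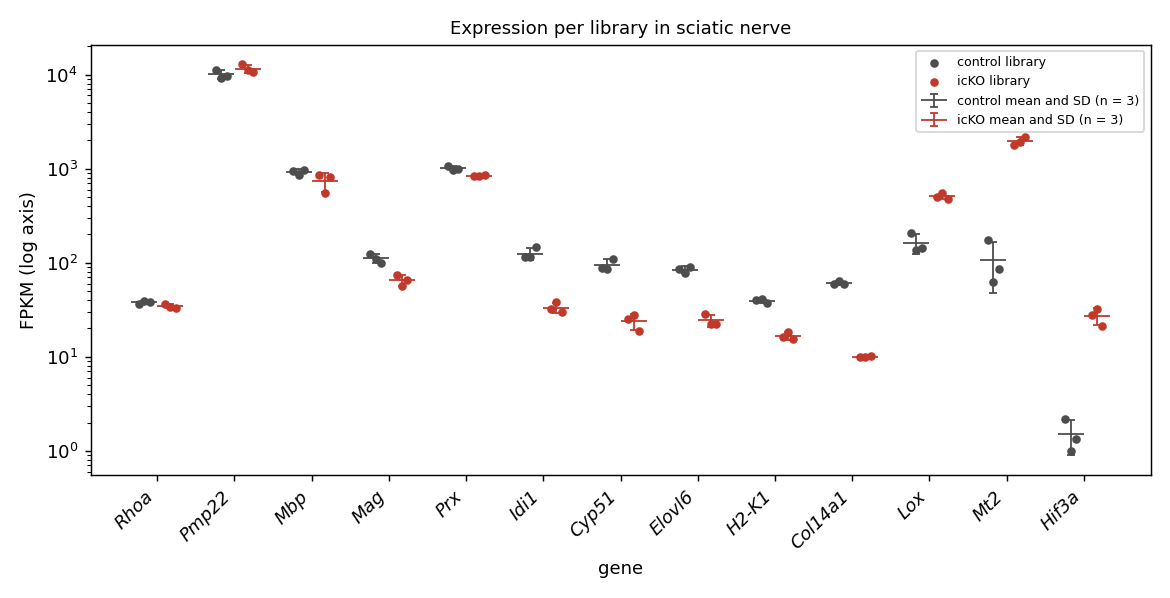
FPKM of 13 genes on a log axis, with 1 point per library, control in grey and icKO in red, and bars for the mean and SD (n = 3 per group). Lox, Mt2 and Hif3a lie higher and Mag, Prx, Idi1, Cyp51, Elovl6, H2-K1 and Col14a1 lower in all 3 icKO libraries than in any control library, as do the points of Rhoa and Mbp, whose differences did not pass, and of Prx, whose fall did not pass once a single library was left out, while those of Pmp22 overlap.

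Genes of the axonal and nodal lists moved in both directions, where 42.9% of all tested genes passed in either direction. Which cells of the lysate these transcripts came from was not measured. In control nerves Sncg, Uchl1, Kcna1 and Kcna2 lay far above the neurofilament genes, so these lists are no measure of axonal RNA alone. Of 15 tested neuronal and axonal genes, 5 rose and 7 fell, also when adjusted over the list alone. The 3 neurofilament genes rose, Nefl from 2.10 ± 0.29 to 12.6 ± 2.86 FPKM, Nefm from 1.14 ± 0.022 to 4.43 ± 0.56 FPKM and Nefh from 3.02 ± 0.52 to 11.1 ± 2.04 FPKM (SD, n = 3 each). Uchl1 fell from 34.7 ± 2.10 to 17.5 ± 1.04 FPKM and Sncg from 295 ± 22.9 to 189 ± 22.4 FPKM. The other members that rose, Gap43 and Prph, passed in 0 and 1 of the 6 fits that left out a library. Among 16 node and paranode genes 3 rose (Kcna1, Kcna2 and Lgi4) and 5 fell (Cadm3, Sptbn1, Cntnap1, Nfasc and Ank2), also adjusted over the list alone. The juxtaparanodal potassium channel genes Kcna1 and Kcna2 rose from 36.8 ± 2.16 to 109 ± 10.99 FPKM and from 39.8 ± 2.39 to 85.5 ± 15.4 FPKM. Cadm3, an adhesion molecule of the internode, fell from 78.5 ± 2.14 to 21.8 ± 2.42 FPKM. Nfasc and Ank2, which also fell, passed in none of the fits that left out a library. Neither list passed as a set (camera, Benjamini-Hochberg adjusted p = 0.7 and 0.77).

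Markers of other Schwann cell states were higher for some genes, where 20.8% of all tested genes rose. Of 15 tested genes of immature and repair Schwann cells 5 rose (Sox2, Gfap, Ncam1, Id2 and Gap43) and 2 fell. Of 10 genes of nonmyelinating Schwann cells 4 rose (Chl1, Scn7a, Gfap and Ncam1) and 2 fell, L1cam and Slc35f1 (5 and 2 in each list when adjusted over the list alone). Sox2, a transcription factor of immature Schwann cells, rose from 3.87 ± 0.38 to 8.99 ± 1.22 FPKM, the intermediate filament gene Gfap from 2.64 ± 0.24 to 15.5 ± 8.68 FPKM, and the sodium channel gene Scn7a from 44.6 ± 3.99 to 92.2 ± 19.6 FPKM (SD, n = 3 each). Mycn fell from 4.92 ± 0.55 to 0.99 ± 0.38 FPKM and L1cam, which both lists hold, from 8.38 ± 0.96 to 4.95 ± 0.31 FPKM. Ngfr was at 16.3 ± 1.79 and 19.3 ± 7.31 FPKM. The sets did not pass (camera, Benjamini-Hochberg adjusted p = 0.46 and 0.35). Id2 and Gap43 passed in only 2 and 0 of the 6 fits that left out a library. The repair count was 3 higher without control replicate 1, control replicate 3 or icKO replicate 1 (3 lower in the last), and 4 higher and 4 lower without icKO replicate 3. Without icKO replicate 2, 7 nonmyelinating genes were higher.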

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

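The fit without the 2 muscle-rich libraries, the muscle covariate and the correction for GC content and length were chosen after the data were seen. The number of genes called was 5516 and stayed within 1.5 times that under each alternative except the filter at a mean of 5 FPKM, which called 3308 of 6888 genes tested, fewer because fewer genes were tested (3234 of the 3251 earlier calls among them were kept). Leaving out single libraries gave 3750 (without control replicate 3) to 5458 (without icKO replicate 3) genes, and an adjusted p of 0.1 gave 6729. Scaling moved the share of higher calls little, from 48.4% to between 48.1 and 50.1%, with counts of 5463 to 5590, and the median of the gene-by-gene shifts in log2 difference was at most 0.014. The share was 43.8% without the 2 muscle-rich libraries (4883 genes), a fit whose remaining control libraries hold more muscle transcripts than the icKO libraries, and 49.5% with the muscle covariate (4802 genes). Genes at unadjusted p and a log2 difference of at least 1 numbered 1003, and 1624 and 1706 with pseudocounts of 0.1 and 0.01, which compress low genes less, 1473 with TPM, whose larger values are compressed less by the same pseudocount, and 582 with the filter at 5 FPKM, where fewer genes were tested. They numbered 905 to 1109 without single libraries. All 9 gene lists called by camera were called in each of 18 alternative fits, which called 9 to 12 lists in all, and camera called 0 lists with an estimated correlation (0 also at an unadjusted p under 0.05). Tested with fry, 11 lists passed, the 9 called by camera and the glycolysis and hypoxia and endothelial lists.

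Rhoa stayed between -0.18 and -0.10 on the log2 scale and did not pass in any alternative. Of 1138 values of the other reported genes of the naming rule under the alternatives, 1122 kept direction and call, 15 were no longer past the threshold (Prx and Kdsr) and 1 changed sign, a difference that had not passed. That was Pmp22 with quantile scaling (0, adjusted p = 1 in limma). Quantile scaling gives genes of equal rank an equal value, so a gene that keeps its rank in every library shows no difference by construction.

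With the replicate number as a replicate block 4596 genes and 9 lists were called, and 1006 genes passed unadjusted p and fold. Same-numbered libraries did not deviate together, with correlations of -0.1, 0.04 and -0.05, which gives no sign that the numbers pair the samples. Such correlations cannot exclude a pairing, as the libraries also differ in muscle content. At an estimated 17200000 to 20600000 fragments a library, values of a few FPKM in short transcripts rest on few fragments, and changes of low genes are the least certain.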

Other observations

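The time-of-day, glucocorticoid, growth and snoRNA host gene lists and the tests of adipose tissue, of batch or litter and of the splits were chosen after results had been seen, as were the GC and muscle corrections and the members named below.

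Members of the glycolysis and hypoxia list moved in both directions. Of 20 tested, 10 fell, 3 rose and 7 did not pass, also when adjusted over the list alone. As a set the list did not pass with camera (Benjamini-Hochberg adjusted p = 0.13) but passed with fry (Benjamini-Hochberg adjusted p = 0.033). Pkm, the last enzyme of glycolysis, fell from 66.4 ± 4.58 to 36.9 ± 1.09 FPKM and Eno1 from 55.4 ± 5.27 to 28.4 ± 2.16 FPKM, while Adm, which encodes a vasodilator peptide, rose from 3.36 ± 0.57 to 11.4 ± 1.77 FPKM (SD, n = 3 each). Of 20 tested genes of the unfolded protein and integrated stress response 4 fell, 3 rose and 13 did not pass (camera adjusted p = 0.77). Among those that fell were Hsp90b1, at 101 ± 8.92 and 54.2 ± 2.97 FPKM, and Hspa5, whose fall did not pass without control replicate 2 or 3. Heat shock genes had 7 lower and 1 higher of 14 (adjusted p = 0.3), and genes of oxidative stress 3 lower and 2 higher of 15, the latter being Mt1 and Mt2 (adjusted p = 0.79). The 1 higher heat shock gene became 0 without control replicate 1 or 3 and 2 without control replicate 2 or icKO replicate 3. Lysosome and autophagy genes split, with 6 of 23 lower and 5 higher (adjusted p = 1). Hexa, a lysosomal hexosaminidase gene, fell from 48.8 ± 5.01 to 11.8 ± 1.89 FPKM, while Sqstm1 and Map1lc3b, which serve autophagy, rose from 68.5 ± 2.89 to 104 ± 8.09 FPKM and from 9.77 ± 0.74 to 15.3 ± 0.30 FPKM. Adjusted over the list alone, the stress, heat shock, oxidative stress and lysosome lists had 4, 7, 2 and 6 members lower and 3, 2, 2 and 5 higher.

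Vascular, basal lamina and other lists moved in parts, and none of the following passed as a set with camera (Benjamini-Hochberg adjusted p = 0.19 to 0.99). The endothelial list passed with fry (Benjamini-Hochberg adjusted p = 0.038). Of 17 endothelial genes 5 fell and 2 rose, also adjusted over the list alone, with Plvap, a protein of fenestrated endothelium, lower at 23.1 ± 2.65 and 8.56 ± 1.04 FPKM (SD, n = 3 each). Of 23 genes of the basal lamina and its receptors 8 fell and 3 rose (9 and 4 over the list alone), with the integrin gene Itga6 lower at 80.4 ± 4.39 and 43.6 ± 6.95 FPKM. The YAP and TAZ list had 4 of 15 higher and 1 lower, also adjusted over the list alone, with Ccn2 higher at 8.38 ± 1.42 and 22.6 ± 5.88 FPKM and Yap1 lower at 12.7 ± 0.46 and 9.60 ± 0.61 FPKM, and 1 to 3 were higher when single libraries were left out. Of 12 cell cycle genes 4 rose and 2 fell, and of 10 perineurial genes 2 fell and 1 rose, with Moxd1 lower at 3.87 ± 1.5 and 0.58 ± 0.20 FPKM. Nuclear respiratory chain genes had 6 of 31 lower and 1 higher, but 11 lower without icKO replicate 3, 3 without control replicate 2 and 2 without control replicate 3, and mitochondrially encoded genes 3 of 13 lower and 1 higher. Among erythroid, mast cell and inflammatory lists, 1, 2 and 1 rose and 1, 0 and 1 fell of 10, 6 and 10 tested, with Kit higher at 1.20 ± 0.33 and 4.74 ± 1.60 FPKM and Ccl7 lower at 7.15 ± 2.29 and 0.23 ± 0.24 FPKM. Adjusted over the list alone, the cell cycle, perineurial, respiratory chain, mitochondrial, erythroid, mast cell and inflammatory lists had 4, 0, 1, 1, 0, 2 and 1 members higher and 2, 2, 4, 3, 1, 0 and 1 lower. When single libraries were left out, 2 cell cycle genes were higher without control replicate 1, 2 or 3 (1 to 3 lower over all 6 fits), and 0 endothelial genes were higher without control replicate 2, control replicate 3 or icKO replicate 2. In 5 of these 6 fits 0 perineurial, 0 mitochondrially encoded and 0 erythroid genes were higher, and 1 to 4 mitochondrially encoded genes were lower. Without control replicate 1, 3 mast cell and 3 inflammatory genes were lower, and 0 inflammatory genes were higher without control replicate 2, control replicate 3 or icKO replicate 1. Of 5 sex-linked genes only Eif2s3y passed, which was listed at 0 in control replicate 2, and none did when adjusted over the list alone. Motor neuron, lymphocyte, neutrophil, keratinocyte, cartilage and histone lists had 3 or fewer tested members and were not tested. Median, mean and direction of the set test differed in sign for the neuronal (-0.23, 0.02, lower), perineurial (0.03, -0.31, lower), cell cycle (-0.14, 0.03, higher), mast cell (-0.62, -0.08, higher) and lysosome (-0.02, -0.07, higher) lists.

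The breadth of the response, 5516 of 12860 genes, was weighed against technical explanations. A trend with GC content or transcript length was argued against as the whole cause, since 5592 genes were called after each library's trend was removed. Carry-over that follows 1 muscle level per library was argued against as the whole cause too. With that level as a covariate 4802 genes were called, and the main calls kept their median absolute log2 difference of 0.59 (0.59 in their direction with the covariate). The covariate does not remove all muscle signal, as 5 of 21 skeletal muscle genes rose and 9 fell with it, against 0 and 1 in the main fit. Myl2 was at 17.9 FPKM in icKO replicate 3 and at 0.03 FPKM or less elsewhere, so carry-over of differing muscle stays open. The fit without the 2 muscle-rich libraries decides nothing on this, as it leaves Acta1 at 61.6 and 80.6 FPKM in control and 2.15 and 6.08 FPKM in icKO libraries. Among the 10 splits of the 6 libraries, 1, the real one, called as many genes, with 1 gene in the highest other split. At unadjusted p and fold 1 gave as many, with 1003 against 60. As many lists came from 6 splits, with 9 against 15, and 10 splits are too few for a share under 0.05. Every other split mixes the genotypes within its groups, so the difference between genotypes enters its residual spread. Low gene counts in those splits are therefore no measure of chance. A different time of day stays open, as the evening arm of the clock had a median log2 difference of 0.02 and the morning arm 0.54, -0.52 apart. The 9 tested evening genes went opposite ways, with Dbp lower (-1.31) and Per2 (0.71) and Per3 (0.36) higher. Per1, which was held in the glucocorticoid list and not in this arm, rose by 2.17. Of the tested morning genes Nfil3, Cry1, Arntl and Clock, only Nfil3 and Cry1 passed. Per3 and Cry1 passed in only 1 and 2 of the 6 fits that left out a library. A batch or litter shared by a group stays open too, since the component that separates the genotypes (66% of the variance) would also separate such batches. Sex was argued against as the whole cause, since 3922 genes were called without control replicate 2, the only library with Xist and without Y-linked transcripts. The labels do not say whether control mice also received the drug that induces Cre, and a difference in drug treatment between the groups was not tested. The genotype named by the design is likewise open, and genotype and an undeclared batch cannot be told apart here.

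The fall of cholesterol and fatty acid synthesis genes came with a fall of adipocyte transcripts. A trend with GC content or length was argued against, since the median log2 difference of the cholesterol list was -1.36 after the correction. Less epineurial fat in the icKO nerves may account for part of the fall. The 4 adipocyte transcripts Adipoq, Fabp4, Plin1 and Cidec fell by a median of 16.0 FPKM and the cholesterol genes by 27.2 FPKM, a ratio of 0.59. The largest single falls were 40.0 FPKM (Adipoq) among the 4 and 282 FPKM among the cholesterol genes. These values depend on the choice of the 4. In the same adipocyte list Cfd (369 to 68.7 FPKM) and Car3 (198 to 24.1 FPKM) fell by more than Adipoq, while Plin4 and Pnpla2 rose. Nor do falls of marker genes show how much RNA of the synthesis genes came from fat. As Adipoq fell by more than the median cholesterol gene and Cfd was at 369 FPKM in control nerves, fat and Schwann cells cannot be told apart as the place of the fall. No adipocyte gene of the list is in either synthesis list, and the genotype stays open as well.

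Several of the largest rises, among them Mt1, Mt2, Hif3a, Map3k6 and Arrdc2, are of a kind induced by glucocorticoids, and raised glucocorticoid or fasting signalling in the icKO mice is a candidate explanation. A list of such targets was written before these values were looked at. Without the 2 genes already named and Ddit4, which a fixed list held, 13 of 13 rose (20.8% of all genes did) with a median log2 difference of 1.90, among them Sgk1 (35.9 ± 15.2 to 230 ± 21.5 FPKM), Tsc22d3 (46.7 ± 14.4 to 174 ± 40.2 FPKM) and Pdk4 (6.71 ± 2.36 to 41.1 ± 5.71 FPKM). Camera gave p = 5.3e-08 with the preset correlation, and p = 0.066 with an estimated correlation, and 2 of the targets, Angptl4 and Bcl6, passed in only 2 of the 6 fits that left out a library. A trend with GC content or length was argued against, as the median was 1.95 after the correction. The result is consistent with a systemic signal in icKO mice, as a hypothesis, but stress, fasting, handling and batch were not separated by any value here, and no hormone was measured.

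For the rise of ribosomal protein genes, delayed growth of the icKO mice was tested on 9 genes of perinatal growth, of which 3 rose (Dlk1, Cdkn1c and Igf2) and 1 fell (Mycn), with a median log2 difference of 0.56 and a camera p of 0.079, which leaves it open. Host genes of small nucleolar RNAs, many of which share the translational control of ribosomal protein genes, rose in 9 of 12 cases with a median of 0.53 (camera p = 2.8e-05, and p = 0.012 with an estimated correlation).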
